A study of Gallus gallus with 12 samples.

How the data were processed

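Gene expression was measured in the primitive streak, the furrow through which cells enter the chick embryo during gastrulation, at stage HH4. Eggs were incubated at 38.5 °C for about 18 h. The sample descriptions also speak of pooled collection every 4 h during 1 day, which the remaining labels do not explain, so the spread of collection times within a pool is unknown. Each streak was cut along its length into 4 equal pieces, here called regions A, B, C and D from the anterior to the posterior end. Pieces of 85 to 93 streaks were pooled per sample. Each of the 4 regions has 3 samples, and samples with the same number came from the same pool of streaks per the labels, so the 12 samples form 3 complete sets of regions. From each sample 5 µg of total RNA was labelled with biotin in a one-cycle reaction, without amplification, and hybridised to an Affymetrix Chicken Genome Array.

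The deposited values are log2 RMA signals, which the authors obtained by background correction, quantile normalization across arrays and a median-polish summary per probe set. Neither the version of RMA nor the chip definition is stated. The unit was checked on the values, which run from about 2.6 to 14.3, and array medians lay between 6.22 and 6.26. Scanned probe intensities and detection calls were not available, so the background of each probe set is unknown and a low signal cannot be told from no signal. For arrays, the number of samples per region, 3, limits the precision.

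Of 38535 probe sets, 37693 with chicken identifiers were tested. The 842 others (96 array controls and 746 for viral or reporter sequences) were left out. Gene symbols came from the platform table of probe sets, which gave 1 symbol to 27166 tested probe sets, several to 177 and none to 10350. No genome build is named for the array, so no positions are given. Where a gene had several probe sets, the one with the highest mean over all arrays stood for it, which left 13008 genes.

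All comparisons came from 1 linear model per probe set, fitted to all 12 arrays with limma 3.58.1 in R 4.3.3. Region and streak pool were terms, the pool number serving as a replicate block, which left 6 residual degrees of freedom and a prior of 5.46. The 6 contrasts tested were: any difference between the 4 regions (F-test), A against D, the neighbouring steps A against B, B against C and C against D, and the mean of the middle regions B and C against the mean of the end regions A and D. Differences are given as the first-named group minus the second on the log2 scale, with the standard error (SE) of the model. P values were adjusted by the Benjamini-Hochberg method within each contrast over the tested probe sets, two-sided, with a threshold of 0.05. No filter on signal was applied. A difference of at least 1 on the log2 scale, which is 2-fold, was counted beside the calls.

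The pairing by pool was checked on the deviation of each array from its region mean. Deviations of arrays from the same pool had a mean correlation across probe sets of 0.012 (18 pairs, from -0.25 to 0.38), against -0.007 for 36 pairs from other pools, and 3 of the 12 arrays were closest to an array of their own pool. The pool term was kept because the labels give it. Probe sets are not independent replicates in these correlations. The deviations cancel out within each region, so the value for other pools largely follows from that for the same pool and is no separate baseline.

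Gene lists for 28 groups of genes were fixed before the data were examined, as were the comparisons, the alternatives and the rule for named genes. They covered node and axial mesendoderm, definitive endoderm, neural plate and epiblast, non-neural ectoderm border, paraxial mesoderm, lateral plate and extraembryonic mesoderm, blood and endothelial progenitors, streak and epithelial-mesenchymal transition, WNT ligands and receptors, WNT target genes, WNT antagonists, BMP ligands and target genes, BMP antagonists, FGF genes, the hedgehog, nodal and activin, notch, and retinoic acid pathways, HOX and CDX genes, germ cells, yolk endoderm and hypoblast, extracellular matrix, cell adhesion and guidance, tight junctions and epithelium, cell cycle, glycolysis and hypoxia, ribosomal proteins, and stress and apoptosis. Several genes belong to more than 1 list. Each list was tested against all other genes with camera (limma) at a preset correlation between genes of 0.01, with adjustment over the 28 lists, and again with the correlation estimated per list. No list passed the threshold with an estimated correlation in any comparison, so each list call carries that second p. The fry test, which asks whether the genes of a list move on balance one way and makes no comparison with other genes, was run beside it. Counts of list members use the adjustment over all tested probe sets unless they are said to be adjusted over the list alone. For scale, 4308 of the 13008 genes with 1 probe set each were called between A and D when adjusted over those genes. Of these, 1914 were higher in A and 2394 lower. A list share near that one is not particular to the list.

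Genes were named by rule: those with a proper symbol, an adjusted p under 0.05 and the same direction in all 3 pools were ranked by size, and the first 12 per direction were taken for A against D and the first 6 for each other contrast. Up to 4 members with the largest difference per list and a set of known streak genes were added, whatever their result. Members named beyond these, to complete small counts, were chosen after their values were seen. For single genes, the alternatives below were run only in the contrasts for which the rule named them. The procedure was tested on simulated data of the same size, with 50 probe sets of 37693 changed at each of 4 sizes between regions A and D. It recovered 80% of those changed by 0.5 on the log2 scale, 96% at 1 and 100% at 2 and at 4, with 6 false calls among 194. The simulated noise was normal and independent between probe sets, with the same spread in every array and no pool effect. These rates may therefore not hold for the real arrays.

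The alternatives were a fit without the replicate block, the pool as a random effect, renewed quantile normalization, median centring, filters on mean signal, an intensity trend or robust estimate in the variance prior, array weights, 1 probe set per gene, the 6 arrays of the compared regions alone, and leaving out each pool and each array. A fit without both arrays that stood apart from their region (region B replicate 1 and region C replicate 3), and list tests without region B replicate 1, were added after seeing the data. Where a fit left 1 region with fewer arrays, its spread was taken from all regions. Results were also counted under other splits of the arrays into groups.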

Results

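Expression was compared along the primitive streak in 12 samples, 3 from each of regions A, B, C and D. Region A is the anterior end, which at this stage carries the node, the organizer of the chick embryo, and region D is the posterior end. Each value is the log2 RMA signal of a probe set, and each named gene is represented by 1 probe set. Arrays of the same region correlated across probe sets at 0.993 to 0.998 and arrays of different regions at 0.981 to 0.997. Probe sets are not independent replicates in these values. The median SD between replicates was 0.071 in region A, 0.088 in B, 0.078 in C and 0.070 in D.

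The regions lay in their anatomical order on the first principal component, which carried 58.1% of the variance. Scores were -33.3 ± 1.7 (SD, n = 3) in region A, -11.4 ± 1.1 in B, 10.1 ± 4.5 in C and 34.5 ± 2.4 in D. The second component carried 10.8% and set region B replicate 1 apart from the other arrays of its region. The F-test called 6551 of 37693 probe sets (17.4%) as different between regions. Of these, 2122 (32.4%) rose in mean at every step from A to D and 1980 (30.2%) fell at every step. The highest mean was in region D for 2981 probe sets (45.5%), in A for 2678 (40.9%), in B for 500 (7.6%) and in C for 392 (6.0%). The count was 3149 without replicate 2 and 4352 without replicate 3, fits in which fewer arrays were tested.

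**Figure D1:**
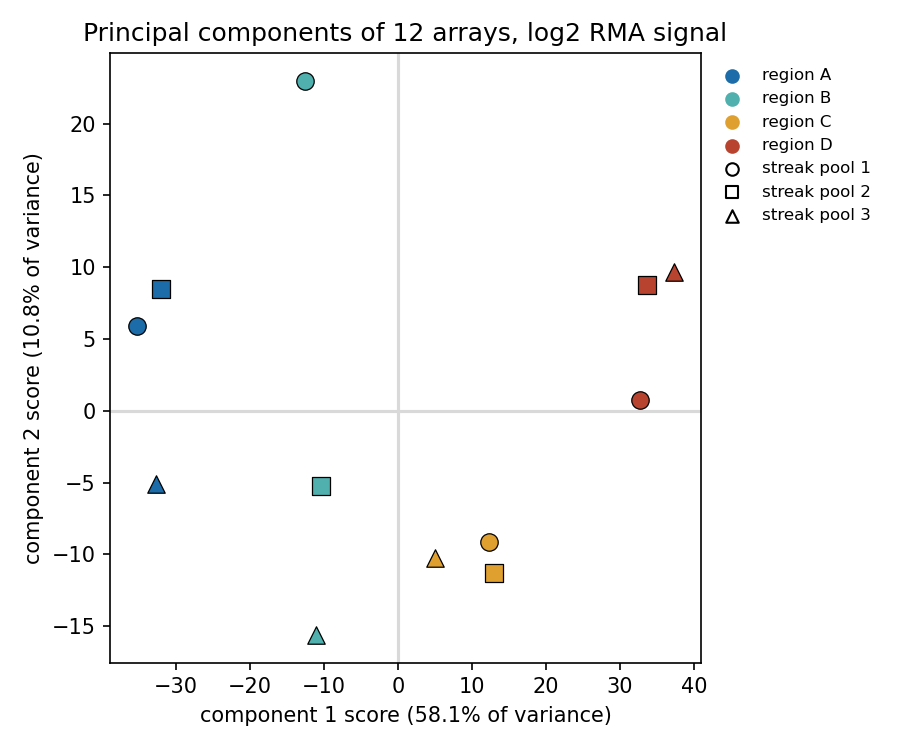
Scores of the 12 arrays on the first (58.1% of variance) and second (10.8%) principal components of the log2 RMA signal, with colour for the region and marker shape for the streak pool. The regions follow each other from A (mean -33.3) to D (mean 34.5) along the first component, and region B replicate 1 lies above the other arrays on the second.

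RNA and hybridisation signs differed a little between regions. The 3' minus 5' signal of the control transcripts averaged 0.17 ± 0.03 (SD, n = 3) in region A, 0.25 ± 0.03 in B, 0.18 ± 0.03 in C and 0.22 ± 0.01 in D. The hybridisation controls averaged 9.57 ± 0.11 in region A, 9.85 ± 0.08 in B, 9.95 ± 0.24 in C and 9.85 ± 0.14 in D.

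The comparison of regions A and D asks how the ends of the streak differ. Of the fixed lists, 13 of 17 node genes were higher in region A, and 15 of 21 BMP ligand and target genes were higher in region D. These lists had adjusted p = 0.105 and adjusted p = 0.104 with an estimated correlation. GSC, a homeobox gene of the organizer, had a signal of 11.39 ± 0.15 (SD, n = 3) in region A, 9.85 ± 0.32 in B, 7.80 ± 0.42 in C and 6.45 ± 0.10 in D. That was 30.7-fold higher in A than in D, a log2 difference of 4.94 ± 0.19 (SE, adjusted p = 1.26e-08). CHRD, which encodes the BMP antagonist chordin, fell from 12.85 ± 0.06 in region A to 8.64 ± 0.15 in D, a difference of 4.21 ± 0.17 (adjusted p = 1.69e-08). In the other direction CDX4, a caudal homeobox gene, had 5.28 ± 0.34 in region A and 10.00 ± 0.10 in D, a log2 difference of -4.73 ± 0.28 (adjusted p = 3.14e-07), with a signal in A below the array medians.

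The largest differences in favour of region A were in FZD8, a WNT receptor gene (5.79 ± 0.28), ADMP, a BMP-like ligand gene of the organizer (5.53 ± 0.26), PKDCCA (5.03 ± 0.24) and OTX2, a homeobox gene of the anterior head (5.01 ± 0.20). Next after GSC and CHRD came the WNT receptor gene FZD5 (4.09 ± 0.23), the forkhead gene FOXD3 (4.01 ± 0.17), the zinc finger gene ZIC2 (4.00 ± 0.14), the endothelin receptor gene EDNRB (3.86 ± 0.09), the LIM homeobox gene LHX1 (3.49 ± 0.20) and TMEFF2 (3.45 ± 0.13). The largest in favour of region D after CDX4 were in HOXA2 (-4.04 ± 0.17), the cytokine signalling inhibitor gene SOCS2 (-3.71 ± 0.10), CDX2 (-3.65 ± 0.25), HOXB1 (-3.17 ± 0.22), MSX2, a BMP-induced homeobox gene (-3.13 ± 0.16), and HOXA9 (-3.07 ± 0.13). WNT5A (-3.03 ± 0.13), BMP7 (-3.003 ± 0.09), the WNT inhibitor gene APCDD1 (-2.96 ± 0.12), MYC (-2.95 ± 0.11) and NOXO1 (-2.95 ± 0.12) followed. Each of these 24 genes differed in the same direction in all 3 pools, which the rule for named genes required.

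Some of these genes have probe sets with very different sizes of difference between A and D. The range over probe sets was 0.16 to 5.79 for FZD8, -0.02 to 4.09 for FZD5, -0.10 to 3.45 for TMEFF2 and 0.64 to 4.00 for ZIC2. It was -4.04 to -0.34 for HOXA2, -3.07 to -0.20 for HOXA9, -4.01 to -0.23 for CDX2, -3.17 to 0.07 for HOXB1 and -3.24 to -0.20 for WNT5A. Among genes named in the lists it was -4.06 to -1.69 for KDR, with all 5 probe sets past the threshold, -2.999 to -0.59 for HOXB3, -2.34 to -1.34 for PIWIL1 and 0.06 to 3.49 for SFRP1. It was -0.19 to 2.56 for FSTL4, -2.00 to -0.10 for DLX5, -1.91 to -0.06 for NOTCH1, -2.92 to -0.59 for MESP1, -2.63 to -0.14 for ALDH1A2 and -1.02 to -0.12 for BMP4. FGFR3 had -1.89 to 0.03, TNFRSF19 -1.09 to -0.02, DHRS3 -1.64 to -0.19, APCDD1 -2.96 to -0.90 and NOXO1 -2.95 to -0.72. BMP7 had -3.003 to -1.76, LMO2 -1.68 to -0.57, SNAI1 1.39 to 2.38 and GADD45G -1.96 to -1.10. No named gene had probe sets past the threshold in opposite directions.

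**Figure D2:**
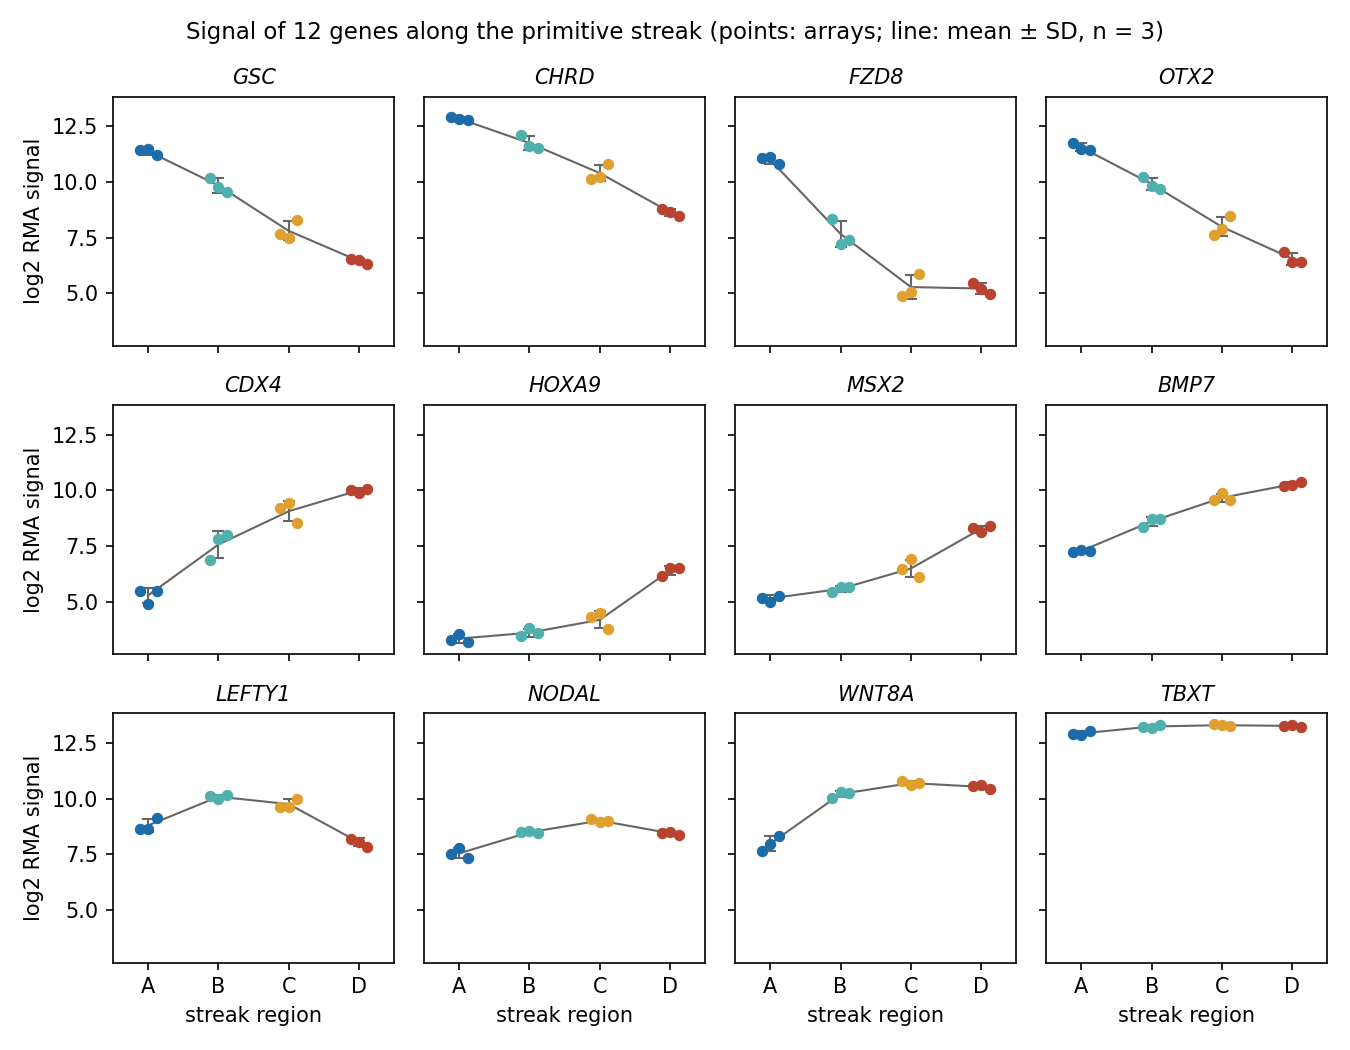
Log2 RMA signal of 12 genes in regions A to D; points are arrays, and lines join region means with bars of 1 SD (n = 3). GSC, CHRD, FZD8 and OTX2 are highest in region A, CDX4, HOXA9, MSX2 and BMP7 in D, and LEFTY1 reaches 10.09 in B against 8.79 in A and 8.04 in D.

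In the node and axial mesendoderm list 13 of 17 measured genes were higher in A and 0 lower (13 and 0 adjusted over the list alone), among them HHEX (3.19 ± 0.19), FOXA2 (2.55 ± 0.15) and SHH, a ligand gene of the node (0.67 ± 0.07). Camera gave this list an adjusted p of 1.74e-13, and adjusted p = 0.105 with an estimated correlation. The definitive endoderm list had 6 higher and 3 lower of 10 (6 and 3 adjusted over the list alone). SOX17 (1.90 ± 0.13) and CXCR4 (2.37 ± 0.10) were among the higher, and the lower were the transcription factor genes GATA5 (-1.83), GATA6 (-0.89) and GATA4 (-0.84). Its adjusted p was 0.0162, and adjusted p = 0.354 with an estimated correlation. Of 15 neural plate and epiblast genes 7 were higher, such as SOX3 (1.97 ± 0.07) and GBX2 (0.46 ± 0.12), and 2 lower, CDH1 (-0.998 ± 0.06) and LIN28A (-0.45), with the same counts adjusted over the list alone (adjusted p = 0.0056, and adjusted p = 0.142 with an estimated correlation).

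Among signalling genes, the BMP antagonist list had 5 higher of 11 and 0 lower (5 and 0 adjusted over the list alone), which were ADMP, CHRD, FSTL4 (2.56 ± 0.09), FST (2.22 ± 0.17) and CHRDL1 (1.16). ADMP is itself a BMP-like ligand. The median over this list was -0.03 against a mean of 1.37 (adjusted p = 0.0072, and adjusted p = 0.142 with an estimated correlation). Of 31 FGF ligand, receptor and feedback genes 13 were higher and 4 lower (14 and 6 adjusted over the list alone). FGF8 (3.08 ± 0.17), FGF18 (2.76 ± 0.14) and the feedback inhibitor gene SPRY1 (2.20 ± 0.11) were higher, and FGFR3 (-1.89 ± 0.18), FGF19 (-1.03), FGF4 (-0.75) and ETV1 (-0.42) were lower. The FGF list had an adjusted p of 0.0085, and adjusted p = 0.142 with an estimated correlation. In the nodal and activin list 9 of 15 were higher, such as EOMES (3.06 ± 0.13), CER1 (2.83 ± 0.12) and CFC1 (1.01 ± 0.07), while the ligand gene NODAL itself was the 1 lower gene (-0.90 ± 0.08). The counts were 9 and 2 adjusted over the list alone (adjusted p = 0.0072, and adjusted p = 0.433 with an estimated correlation).

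In the BMP ligand and target list 15 of 21 genes were lower in A and 0 higher (15 and 1 adjusted over the list alone), among them MSX1 (-2.15 ± 0.09), SMAD6 (-2.07 ± 0.09) and BMP4 (-1.02 ± 0.09), with an adjusted p of 4.36e-09 and adjusted p = 0.104 with an estimated correlation. Of 31 HOX and CDX genes 16 were lower in A and 0 higher. With 17 and 0 adjusted over the list alone, the list had adjusted p = 2.56e-07, and adjusted p = 0.142 with an estimated correlation. Within the HOXB cluster HOXB5 (-2.05 ± 0.12), HOXB4 (-1.11 ± 0.14), HOXB3 (-0.59 ± 0.07) and HOXB2 (-0.48 ± 0.07) were lower in A. The other probe set of HOXB3 had -2.999, so the order within the cluster depends on the probe set. HOXB6 (-0.12, adjusted p = 0.285), HOXB7 (-0.06, 0.723), HOXB8 (-0.01, 0.917) and HOXB13 (-0.12, 0.212) did not pass. Signals of HOXB6, HOXB7 and HOXB8 lay below the array medians on every array, so even expression of these 3 genes cannot be told from no signal. The lateral plate and extraembryonic mesoderm list had 15 lower and 1 higher of 22 (15 and 1 adjusted over the list alone). HAND2 (-2.09) and HAND1 (-0.50 ± 0.08) were lower, and SNAI1, a repressor of epithelial genes, was higher (2.38 ± 0.19). This list had an adjusted p of 5.86e-07, and adjusted p = 0.105 with an estimated correlation. Of 15 WNT target genes 9 were lower in A, such as CDX1 (-1.70 ± 0.16), AXIN2 (-1.54 ± 0.10) and TNFRSF19 (-1.09 ± 0.11), and 0 higher. Counts were 10 and 0 adjusted over the list alone (adjusted p = 2.39e-05, and adjusted p = 0.142 with an estimated correlation). The non-neural ectoderm border list had 4 lower of 12 and 0 higher, namely MSX2, MSX1, DLX5 (-2.00 ± 0.13) and TFAP2A (-0.53 ± 0.08), with the same counts adjusted over the list alone (adjusted p = 0.0247, and adjusted p = 0.252 with an estimated correlation).

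The 10 further lists of signalling pathways or cell types did not pass camera between A and D. The WNT ligand and receptor list had 5 higher and 9 lower of 29 (5 and 10 adjusted over the list alone; adjusted p = 0.254). Receptor genes made up the higher members, FZD8, FZD5, FZD7 (1.69), FZD1 (0.40) and FZD3 (0.37), and the ligand genes WNT5A, WNT8A (-2.56 ± 0.13) and WNT3A (-2.24) were lower. WNT antagonists had 5 higher, such as SFRP1 (2.98 ± 0.15) and SHISA2 (1.67 ± 0.07), and 2 lower of 14, APCDD1 and NOTUM (-1.08), with the same counts adjusted over the list alone (adjusted p = 0.275; median -0.04, mean 0.30). The retinoic acid list had 4 higher and 6 lower of 14, also over the list alone (adjusted p = 0.345). The synthesis gene ALDH1A3 (1.61 ± 0.15) and the degradation gene CYP26A1 (1.26 ± 0.12) were higher in A, together with STRA6 (1.32) and CYP26C1 (1.02), and the synthesis genes ALDH1A2 (-2.58 ± 0.14) and RDH10 (-1.38 ± 0.08) were lower.

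The streak and epithelial-mesenchymal transition list had 7 higher and 12 lower of 24 (9 and 12 adjusted over the list alone; adjusted p = 0.275). TBXT, the brachyury gene of the whole streak, was near the top of the range in every region, from 12.94 ± 0.11 (SD, n = 3) in A to 13.31 ± 0.03 in C, with a difference between A and D of -0.33 ± 0.07 (adjusted p = 0.00272). MIXL1 was higher in A by 0.32 ± 0.10 (adjusted p = 0.0358), and SNAI2 was lower (-1.51 ± 0.19). Paraxial mesoderm genes numbered 5 higher and 5 lower of 18 (5 and 7 adjusted over the list alone; adjusted p = 0.987). FOXC1 (1.47 ± 0.17), EPHA4 (1.23 ± 0.13), HES6 (0.73), MEOX1 (0.41) and RIPPLY2 (0.32) were higher, and MESP1 (-2.92 ± 0.11), PCDH8 (-1.69 ± 0.14), SNAI2, DLL1 (-1.45 ± 0.24) and PAX3 (-0.34) were lower. TBX6 (0.03 ± 0.14, adjusted p = 0.920) and MSGN1 (-0.60 ± 0.24, adjusted p = 0.102) did not pass, though without pool 3 MSGN1 had -1.02 and passed.

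The blood and endothelial list had 6 higher and 9 lower of 24 (6 and 10 adjusted over the list alone; adjusted p = 0.397). FLI1 (-2.90 ± 0.10), KDR (-1.69 ± 0.12), which encodes a VEGF receptor, and LMO2 (-1.68 ± 0.17) were lower in A. The 5 probe sets of KDR ran from -4.06 to -1.69, and the value given is the smallest. TAL1 (-0.12 ± 0.09, adjusted p = 0.439) and GATA2 (-0.04 ± 0.06, adjusted p = 0.744) did not pass and had signals below 6 in all regions. Notch genes numbered 2 higher, HES4 (0.77) and HES6, and 5 lower of 19, NOTCH1 (-1.91 ± 0.13), NRARP (-1.66 ± 0.12), HEY1 (-1.50 ± 0.08), DLL1 and HEY2 (-0.35), with the same counts adjusted over the list alone (adjusted p = 0.535; median 0.01, mean -0.27). In the hedgehog list SHH, SCUBE1 (0.39 ± 0.07) and BOC (0.23 ± 0.07) were higher and SUFU (-0.21 ± 0.05) lower of 14, also over the list alone (adjusted p = 0.285). Germ cell genes numbered 4 higher, CXCR4, PRDM1 (1.13 ± 0.10), DAZL (0.86 ± 0.13) and KIT (0.57), and 2 lower of 9, PIWIL1 (-1.34 ± 0.11) and DDX4 (-0.57), also over the list alone (adjusted p = 0.453; median -0.06, mean 0.29). The yolk endoderm and hypoblast list had 4 higher, HHEX, CER1, SOX17 and VTN (0.52), and 8 lower of 23 (4 and 9 adjusted over the list alone; adjusted p = 0.579; median -0.04, mean 0.13, direction of the test down).

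**Figure D3:**
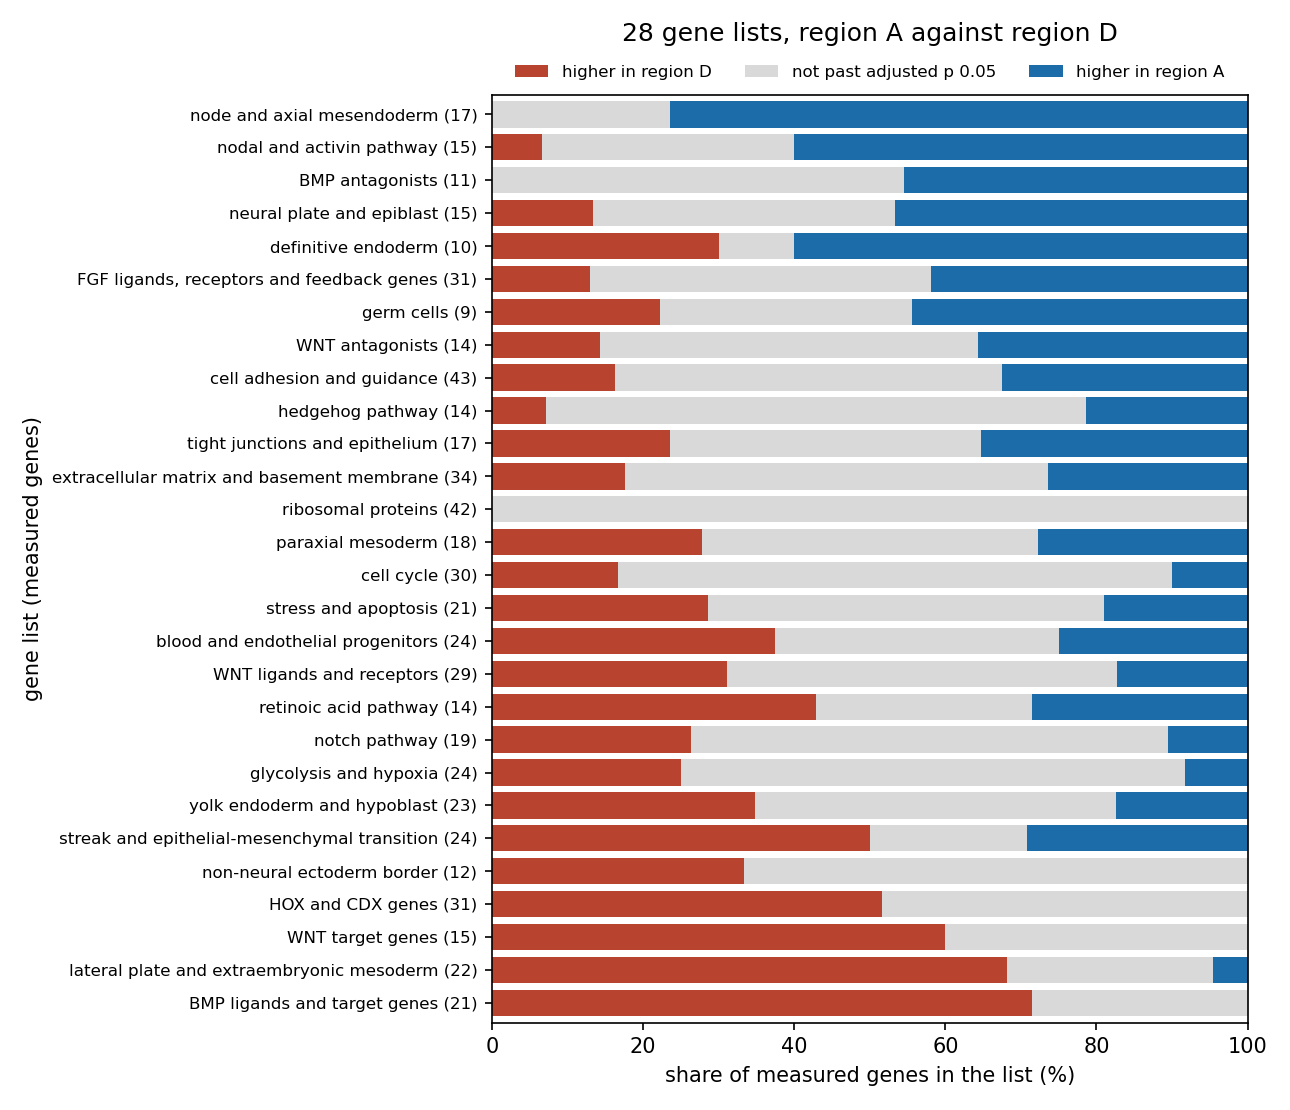
Share of the measured genes of each of the 28 lists (number in brackets) that passed an adjusted p of 0.05 in region A against region D, with blue for higher in A, red for higher in D and grey for neither. In the node and axial mesendoderm list 13 of 17 genes are higher in A, and in the BMP ligand and target list 15 of 21 are higher in D.

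Between A and D limma called 7793 probe sets (20.7%), 3769 higher in A and 4024 lower, of which 447 and 370 differed by at least 1 on the log2 scale. Camera called 11 lists, 6 up and 5 down, none with an estimated correlation, and fry called 21. The count of probe sets was 4844 without replicate 2, a fit with 8 arrays. Higher calls outnumbered lower ones without replicate 2 (2485 and 2359), without replicate 3 (2829 and 2737), without region D replicate 2 (3101 and 3062) and in the 6 arrays of A and D alone (4240 and 4158). Calls of TBXT, BOC, MIXL1 and SUFU were lost without replicate 2, those of BOC, MIXL1 and SUFU also without replicate 3, and those of MIXL1 and SUFU without replicate 1 as well. BOC also lost its call without the replicate block, and MIXL1 (0.15) and SUFU (-0.12) theirs with the mean of their probe sets.

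The step from region A to region B compares the tip of the streak with the tissue just behind it. Of 17 node genes 11 were higher in A, and 9 of 21 BMP ligand and target genes were higher in B. These lists had adjusted p = 0.0845 and adjusted p = 0.0535 with an estimated correlation. FZD8 fell from 11.001 ± 0.18 (SD, n = 3) in A to 7.67 ± 0.60 in B, which is 10.1-fold (3.33 ± 0.28, adjusted p = 5.67e-05). The ligand gene WNT8A rose from 7.97 ± 0.32 to 10.21 ± 0.15 and was 4.72-fold lower in A (-2.24 ± 0.13, adjusted p = 4.55e-06). SHH stood at 7.27 ± 0.17 in A and at 6.58 ± 0.10, 6.56 ± 0.05 and 6.60 ± 0.02 in B, C and D, so that its difference lay in this step (0.69 ± 0.07, adjusted p = 0.000316). Beside FZD8 the largest differences in favour of A were in ARHGAP15 (2.71 ± 0.14), FOXD3 (2.38 ± 0.17), the corticotropin-releasing hormone receptor gene CRHR1 (2.11 ± 0.07), PKDCCA (2.10 ± 0.24) and ADMP (2.03 ± 0.26). In favour of B they were in CDX4 (-2.29 ± 0.28), WNT8A, HOXB1 (-2.04 ± 0.22), CDX2 (-1.87 ± 0.25), MYC (-1.81 ± 0.11) and the matrix linker gene HAPLN1 (-1.68 ± 0.08).

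The node list had 11 higher in A and 0 lower of 17 (11 and 0 adjusted over the list alone; adjusted p = 3.01e-16, and adjusted p = 0.0845 with an estimated correlation), and the definitive endoderm list 5 and 2 of 10. With 5 and 2 adjusted over the list alone, the list had adjusted p = 0.0378, and adjusted p = 0.393 with an estimated correlation. BMP antagonists had 4 higher and 0 lower of 11, ADMP, CHRD (1.10), FSTL4 (0.98) and FST (0.81), with the same counts adjusted over the list alone (adjusted p = 0.000552, and adjusted p = 0.0845 with an estimated correlation). FGF genes had 7 higher and 2 lower of 31. Counts were 11 and 2 adjusted over the list alone (adjusted p = 0.0163, and adjusted p = 0.141 with an estimated correlation). Lower in A were 9 of 21 BMP ligand and target genes, such as MSX1 (-1.47) and BMP7 (-1.33), and 0 were higher. With 11 and 0 adjusted over the list alone, the list had adjusted p = 8.39e-12, and adjusted p = 0.0535 with an estimated correlation. WNT targets had 5 lower of 15, CDX2, MSGN1 (-1.42), AXIN2 (-1.03), SP8 (-0.71) and TBXT (-0.31), and 0 higher. Counts were 10 and 0 adjusted over the list alone (adjusted p = 5.17e-09, and adjusted p = 0.0845 with an estimated correlation).

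The lateral plate list had 5 lower and 1 higher of 22 (7 and 1 adjusted over the list alone; adjusted p = 2.06e-06, and adjusted p = 0.0845 with an estimated correlation), the streak list 8 lower and 3 higher of 24 (12 and 3 adjusted over the list alone; adjusted p = 0.0019, and adjusted p = 0.0849 with an estimated correlation) and WNT ligands and receptors 5 lower and 2 higher of 29. With 7 and 3 adjusted over the list alone, the list had adjusted p = 0.0163, and adjusted p = 0.177 with an estimated correlation. In the streak list SNAI1 (1.16), EOMES (0.71) and VIM (0.58) were higher in A. In the border list the 2 lower of 12 were DLX5 (-1.56) and MSX1, with 0 higher and the same counts adjusted over the list alone (adjusted p = 0.0017, and adjusted p = 0.111 with an estimated correlation). In the HOX and CDX list the 3 lower of 31 were CDX4, HOXB1 and CDX2, with 0 higher and the same counts adjusted over the list alone (adjusted p = 0.006, and adjusted p = 0.393 with an estimated correlation).

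In this step limma called 1067 probe sets, 613 higher in A and 454 lower, with 69 and 46 of at least 1 on the log2 scale; camera called 11 lists and fry 12. The 3' minus 5' signal of the control transcripts was 0.17 ± 0.03 (SD, n = 3) in A and 0.25 ± 0.03 in B. The count fell to 494, 683 and 667 without region A replicates 1, 2 and 3, to 688 and 692 without region B replicates 2 and 3, and to 585, 324 and 587 without pools 1, 2 and 3. Lower calls outnumbered higher ones in the upper quartile by mean level (317 higher and 355 lower). The calls of ADMP and CDX2 were lost without replicate 2. With the mean of their probe sets FZD8 had 1.71 and HOXB1 -0.82.

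The step from region B to region C crosses the middle of the streak. Of 17 node genes 11 were higher in B (adjusted p = 0.106 with an estimated correlation). GSC was 4.12-fold higher in B than in C (2.04 ± 0.19, adjusted p = 0.000391). HOXA2, a hindbrain and branchial arch HOX gene in later embryos, stood at 4.71 ± 0.04 (SD, n = 3) in A, 5.20 ± 0.31 in B, 7.31 ± 0.36 in C and 8.74 ± 0.34 in D, and was lower in B than in C (-2.11 ± 0.17, adjusted p = 0.000221), with signals below the array medians in A and B. Largest in favour of B were FZD8 (2.39 ± 0.28), ADMP (2.31 ± 0.26), FZD5 (2.08 ± 0.23), GSC, PKDCCA (1.99 ± 0.24) and OTX2 (1.93 ± 0.20). In favour of C followed CDX4 (-1.50 ± 0.28), SOCS2 (-1.29 ± 0.10), NOXO1 (-1.28 ± 0.12), CDX2 (-1.24 ± 0.25) and APCDD1 (-1.17 ± 0.12).

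The node list had 11 higher in B and 0 lower of 17. Counts were 12 and 0 adjusted over the list alone (adjusted p = 1.99e-13, and adjusted p = 0.106 with an estimated correlation). Definitive endoderm genes had 6 higher and 0 lower of 10 (6 and 2 adjusted over the list alone; adjusted p = 7.8e-05, and adjusted p = 0.176 with an estimated correlation), among them SOX17 (1.12) and CXCR4 (1.02). BMP antagonists had 4 higher and 0 lower of 11, ADMP, CHRD (1.35), FST (0.82) and FSTL4 (0.67). With 5 and 0 adjusted over the list alone, the list had adjusted p = 0.000143, and adjusted p = 0.106 with an estimated correlation. In the neural plate list OTX2, ZIC2 (1.53) and SOX3 (0.39) were the 3 higher of 15, with 0 lower. Counts were 3 and 2 adjusted over the list alone (adjusted p = 0.0111, and adjusted p = 0.185 with an estimated correlation). In the nodal list CER1 (1.13), FST and EOMES (0.72) were the 3 higher of 15 and NODAL the 1 lower (-0.52). With 4 and 1 adjusted over the list alone, the list had adjusted p = 0.0436, and adjusted p = 0.516 with an estimated correlation.

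Lower in B were 8 of 21 BMP ligand and target genes, with 0 higher (10 and 1 adjusted over the list alone; adjusted p = 1.24e-08, and adjusted p = 0.106 with an estimated correlation), and 4 of 31 HOX and CDX genes, HOXA2, CDX4, CDX2 and HOXA6 (-0.43), with 0 higher. Counts were 8 and 0 adjusted over the list alone (adjusted p = 2.9e-05, and adjusted p = 0.185 with an estimated correlation). The lateral plate list had 6 lower and 1 higher of 22. With 9 and 1 adjusted over the list alone, the list had adjusted p = 3.54e-05, and adjusted p = 0.151 with an estimated correlation. WNT targets had 3 lower of 15, CDX2, AXIN2 (-0.50) and NOTUM (-0.32), and 0 higher. Counts were 6 and 0 adjusted over the list alone (adjusted p = 0.000245, and adjusted p = 0.185 with an estimated correlation). The border list had 2 lower of 12, MSX2 (-0.92) and MSX1 (-0.68), and 0 higher (3 and 1 adjusted over the list alone; adjusted p = 0.0207, and adjusted p = 0.204 with an estimated correlation), and the streak list 7 lower and 4 higher of 24. With 11 and 4 adjusted over the list alone, the list had adjusted p = 0.0297, and adjusted p = 0.185 with an estimated correlation. Ribosomal protein genes passed camera as lower in B with a mean of -0.06 (adjusted p = 0.000486, and adjusted p = 0.516 with an estimated correlation), although 0 of 42 passed alone, also over the list alone.

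From B to C limma called 640 probe sets, 287 higher in B and 353 lower, with 44 and 24 of at least 1 on the log2 scale; camera called 12 lists and fry 8. The 3' minus 5' signal of the control transcripts was 0.25 ± 0.03 (SD, n = 3) in B and 0.18 ± 0.03 in C. The count fell to 404 without region B replicate 2, to 174 and 190 without region C replicates 1 and 2, and to 146 and 55 without pools 1 and 2, and the 6 arrays of B and C alone gave 200. Higher calls outnumbered lower ones without region C replicate 3 (559 and 318), without region B replicate 3 (245 and 183), without replicate 3 (447 and 241), without both region B replicate 1 and region C replicate 3 (381 and 236), a fit chosen after seeing the data, and with array weights (452 and 379). Without replicate 2 the calls of ADMP, FZD5, FZD8, OTX2, PKDCCA, APCDD1, CDX2 and CDX4 were lost, those of CDX2, CDX4 and PKDCCA also without replicate 1. With the mean of their probe sets FZD8 had 1.23, FZD5 0.87, HOXA2 -1.17 and NOXO1 -0.80.

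The step from region C to region D compares the posterior streak with its most posterior end. Of 15 nodal and activin genes 7 were higher in C, and 8 of 31 HOX and CDX genes were higher in D. These lists had adjusted p = 0.191 and adjusted p = 0.150 with an estimated correlation. HOXA9 was low in A (3.33 ± 0.19, SD, n = 3), B (3.60 ± 0.18) and C (4.18 ± 0.39) and reached 6.40 ± 0.21 in D (-2.22 ± 0.13, adjusted p = 9.46e-06), with signals below the array medians outside D. FLI1, an ETS factor gene of blood and endothelial precursors, rose from 7.20 ± 0.17 to 8.93 ± 0.14 (-1.73 ± 0.10, adjusted p = 7.4e-06). FGF8 fell from 8.63 ± 0.35 to 6.95 ± 0.20 (1.69 ± 0.17, adjusted p = 0.0002). Largest in favour of C were ZIC2 (1.97 ± 0.14), EDNRB (1.95 ± 0.09), FGF18 (1.80 ± 0.14), CHRD (1.76 ± 0.17), LEFTY1 (1.72 ± 0.13) and FGF8. In favour of D, beside HOXA9 and FLI1, were GPD1L2 (-1.99 ± 0.18), BPIFCB (-1.80 ± 0.16), MSX2 (-1.79 ± 0.16) and ALDH1A1 (-1.72 ± 0.14), a gene of retinal oxidation.

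The nodal and activin list had 7 higher in C and 0 lower of 15 (9 and 2 adjusted over the list alone; adjusted p = 9.07e-06, and adjusted p = 0.191 with an estimated correlation), among them LEFTY1, EOMES (1.63), CER1 (1.54) and NODAL (0.57). FGF genes had 7 higher and 2 lower of 31, the latter FGFR3 (-0.74) and FLRT3 (-0.68). Counts were 11 and 3 adjusted over the list alone (adjusted p = 0.000308, and adjusted p = 0.150 with an estimated correlation). The node list had 8 higher and 0 lower of 17 (9 and 1 adjusted over the list alone; adjusted p = 5.16e-08, and adjusted p = 0.150 with an estimated correlation), and the neural plate list 7 higher and 1 lower of 15, CDH1 (-0.33). With 7 and 1 adjusted over the list alone, the list had adjusted p = 0.000206, and adjusted p = 0.150 with an estimated correlation.

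Higher in D were 6 of 24 blood and endothelial genes, such as LMO2 (-1.01) and KDR (-0.93), with 0 lower. Counts were 9 and 1 adjusted over the list alone (adjusted p = 0.0116, and adjusted p = 0.226 with an estimated correlation). Of the retinoic acid genes 5 of 14 were higher in D and 0 lower. With 8 and 1 adjusted over the list alone, the list had adjusted p = 0.0021, and adjusted p = 0.350 with an estimated correlation. The 5 genes were ALDH1A2 (-1.43), the receptor gene RARB (-0.89), DHRS3 (-0.56), CRABP1 (-0.40) and CYP26B1 (-0.39). HOX and CDX genes had 8 higher in D and 0 lower of 31 (13 and 0 adjusted over the list alone; adjusted p = 2.44e-06, and adjusted p = 0.150 with an estimated correlation), such as HOXB5 (-1.50), HOXA2 (-1.43) and HOXB4 (-0.72). BMP ligand and target genes had 5 higher in D and 0 lower of 21, MSX2, SMAD6 (-1.28), BMP7 (-0.61), BMP2 (-0.55) and ID2 (-0.39) (8 and 0 adjusted over the list alone; adjusted p = 0.000448, and adjusted p = 0.150 with an estimated correlation), and the lateral plate list 8 and 0 of 22. Counts were 10 and 0 adjusted over the list alone (adjusted p = 0.000161, and adjusted p = 0.150 with an estimated correlation).

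In the same step 5 of 23 yolk endoderm and hypoblast genes were higher in D, APOA1 (-1.05), FGB (-0.78), GATA6 (-0.67), HNF4A (-0.59) and FGG (-0.33), and CER1 was lower. That list did not pass camera (adjusted p = 0.0889).

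From C to D limma called 1863 probe sets, 789 higher in C and 1074 lower, with 42 and 70 of at least 1 on the log2 scale; camera called 9 lists and fry 12. The count fell to 1208 and 1107 without region C replicates 1 and 2, to 1109 and 931 without region D replicates 2 and 3, and to 505 and 832 without pools 2 and 3. With array weights it rose to 3206. Higher calls outnumbered lower ones without replicate 1 (691 and 664) and with median centring (888 and 877). With the mean of their probe sets ZIC2 had 1.05 and HOXA9 -1.18.

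The comparison of the middle regions B and C with the end regions A and D sets the mean of the middle against the mean of the ends, so it takes in genes that peak or dip along the streak and genes in which 1 end departs from the rest. LEFTY1, a secreted inhibitor of nodal signalling, peaked in the middle, with 8.79 ± 0.29 (SD, n = 3) in A, 10.09 ± 0.10 in B, 9.76 ± 0.21 in C and 8.04 ± 0.19 in D (1.51 ± 0.10, 2.84-fold, adjusted p = 3.92e-05). NODAL was highest in C, with 7.54 ± 0.22, 8.49 ± 0.05, 9.01 ± 0.08 and 8.44 ± 0.06 from A to D (0.76 ± 0.06, adjusted p = 0.000114). MSGN1, a gene of presomitic mesoderm, had 9.37 ± 0.77, 10.79 ± 0.42, 10.91 ± 0.11 and 9.97 ± 0.09 (1.18 ± 0.17, adjusted p = 0.0034). FAM84B was also higher in both middle regions than at either end (0.94 ± 0.05), but the mean of its 4 probe sets gave 0.26.

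Other genes passed mainly because 1 end differed from the remaining regions. WNT8A (1.21 ± 0.09), SPAM1 (0.94 ± 0.15) and HOXB1 (0.91 ± 0.16) were far lower in A than elsewhere. FZD8 (-1.63 ± 0.20), ARHGAP15 (-1.36 ± 0.10) and FOXD3 (-1.005 ± 0.12) were far higher in A, and HOXA9 (-0.97 ± 0.10), GPD1L2 (-0.93 ± 0.12) and BPIFCB (-0.92 ± 0.12) in D. WNT8A, for example, had 7.97 ± 0.32 (SD, n = 3) in A and 10.21 ± 0.15, 10.70 ± 0.07 and 10.53 ± 0.10 in B, C and D.

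Higher in the mean of the middle regions were 5 of 24 streak genes, WNT8A, NODAL, FGF8 (0.66), EOMES (0.46) and CDH2 (0.39), and 0 were lower. With 10 and 1 adjusted over the list alone, the list had adjusted p = 4.35e-06, and adjusted p = 0.0818 with an estimated correlation. The nodal and activin list had 4 higher of 15, LEFTY1, NODAL, CER1 (0.70) and EOMES, and 0 lower. Counts were 6 and 2 adjusted over the list alone (adjusted p = 0.000497, and adjusted p = 0.298 with an estimated correlation). Paraxial mesoderm genes had 3 higher of 18, MSGN1, MESP1 (0.43) and EPHA4 (0.42), and 0 lower. With 5 and 3 adjusted over the list alone, the list had adjusted p = 0.000619, and adjusted p = 0.298 with an estimated correlation. WNT targets had 3 higher of 15, MSGN1, SP8 (0.60) and AXIN2 (0.51), and 0 lower. Counts were 7 and 2 adjusted over the list alone (adjusted p = 0.000619, and adjusted p = 0.298 with an estimated correlation). The neural plate list had 2 higher of 15, ZIC2 (0.74) and GBX2 (0.48), and 0 lower. With 2 and 1 adjusted over the list alone, the list had adjusted p = 0.0253, and adjusted p = 0.298 with an estimated correlation. BMP ligand and target genes had 4 higher and 2 lower of 21 (7 and 3 adjusted over the list alone; adjusted p = 0.0253, and adjusted p = 0.298 with an estimated correlation): MSX1 (0.73), BMP7 (0.36), BAMBI (0.34) and ID4 (0.32) were higher, and MSX2 (-0.68) and SMAD6 (-0.46) lower. In the border list MSX1 and DLX5 (0.70) were higher and MSX2 lower of 12. Counts were 3 and 1 adjusted over the list alone (adjusted p = 0.0353, and adjusted p = 0.298 with an estimated correlation).

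Lower in the mean of the middle regions were 5 of 14 retinoic acid genes, with 0 higher. With 7 and 1 adjusted over the list alone, the list had adjusted p = 0.000802, and adjusted p = 0.298 with an estimated correlation. CYP26A1 (-0.74) and ALDH1A3 (-0.60) were highest in A, and the others were ALDH1A2 (-0.61), RARB (-0.41) and CYP26B1 (-0.31). Blood and endothelial genes had 4 lower of 24, HHEX (-0.82), FLI1 (-0.64), KDR (-0.38) and ETS1 (-0.37), and 0 higher. Counts were 9 and 1 adjusted over the list alone (adjusted p = 0.0036, and adjusted p = 0.298 with an estimated correlation). Stress and apoptosis genes had 4 lower of 21, GADD45G (-0.46), GADD45A (-0.36), HSPA5 (-0.36) and ATF3 (-0.31), and 0 higher. With 5 and 0 adjusted over the list alone, the list had adjusted p = 0.0135, and adjusted p = 0.308 with an estimated correlation. The yolk endoderm and hypoblast list had 4 lower, HHEX, APOA1 (-0.65), FGB (-0.41) and HNF4A (-0.28), and 1 higher of 23, CER1. Counts were 7 and 2 adjusted over the list alone (adjusted p = 0.0138, and adjusted p = 0.298 with an estimated correlation). HOX and CDX genes had 3 lower, HOXA9, HOXB5 (-0.68) and HOXA6 (-0.41), and 1 higher of 31, HOXB1. With 7 and 3 adjusted over the list alone, the list had adjusted p = 0.0355, and adjusted p = 0.490 with an estimated correlation.

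Only some of these list members had means in both middle regions that lay beyond those of both ends. Region means of LEFTY1, NODAL, MSGN1, CDH2, SP8, GBX2 and ID4 were higher in both B and C than in A and D, and those of CYP26B1, ETS1, HSPA5, ATF3, APOA1 and FGB were lower. Some of these gaps were small. FGB had 4.80, 4.75, 4.77 and 5.54 from A to D, and APOA1 10.33, 10.08, 10.15 and 11.20, so mainly D departed in both. The mean of NODAL in B was only slightly above that in D. Means of FGF8, EOMES, CER1, EPHA4 and ZIC2 decreased at every step from A to D and were highest in A, with the steepest step from C to D. Means of MESP1, AXIN2, MSX1, BMP7, BAMBI and DLX5 increased at every step, with the steepest step from A to B. Among the members with a lower mean in the middle, MSX2, SMAD6, ALDH1A2, RARB, FLI1, KDR, GADD45G, HNF4A, HOXA9 and HOXB5 increased in mean at every step, and HHEX and GADD45A decreased.

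For middle against ends limma called 767 probe sets, 332 higher in the mean of the middle regions and 435 lower, with 3 and 8 of at least 1 on the log2 scale; camera called 12 lists and fry 5. The count fell to 428 and 506 without region A replicate 1 and region D replicate 3 and to 506, 162 and 372 without pools 1, 2 and 3, and it rose to 1461 without region B replicate 1 and region C replicate 3, a fit chosen after seeing the data, and to 1516 with array weights. Higher calls outnumbered lower ones with renewed quantile normalization (421 and 420), with median centring (398 and 376), in the upper quartile by mean level (262 and 177), without replicate 2 (84 and 78) and without replicate 3 (190 and 182).

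Many of these gene calls were lost when 1 pool was left out. The alternatives were not run in this contrast for CDH2, EPHA4, ID4, BAMBI, ETS1, CYP26B1, HNF4A and HOXA6, so the stability of these calls is unknown. The call of KDR was lost without any 1 of the pools, with renewed quantile normalization and with the mean of its probe sets, and that of MESP1 without pools 1 and 2 and with the mean of its probe sets (0.17). Without pool 2 the calls of MSGN1, SPAM1, HOXB1, FZD8, GPD1L2, BPIFCB, FOXA2, HHEX, CYP26A1, ALDH1A2, ALDH1A3, RARB and APOA1 were lost. So were those of FGF8, EOMES, ZIC2, GBX2, SP8, AXIN2, BMP7, GADD45A, HSPA5 and ATF3. Without pool 1 the calls of EOMES, GBX2, MSX2, SP8, RARB and FGB were lost, and without pool 3 those of BPIFCB, SHH, MSX2, ALDH1A3, FGB, GADD45A, HSPA5 and ATF3. With the mean of their probe sets BMP7 and RARB did not pass, while HOXB1 had 0.37, FZD8 -0.84, HOXA9 -0.53, ZIC2 0.33 and DLX5 0.34. SP8 did not pass without the replicate block. The border and neural plate lists did not pass without pools 2 and 3, the BMP list without pools 1 and 2, the stress list without pool 2 and the HOX and CDX list without pool 3. The HOX and CDX list turned direction among genes above the median mean level, with a mean of 0.128, and did not pass there, nor did the border list. With the mean of all probe sets of a gene the border, BMP and HOX and CDX lists did not pass, and with the probe set of largest interquartile range the border and BMP lists. Without region B replicate 1, a fit chosen after seeing the data, the BMP and the HOX and CDX lists did not pass.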

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

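The fits without region B replicate 1, alone for the list tests or together with region C replicate 3, were chosen after seeing the data; all other alternatives were planned. Without the replicate block the counts were 7910 for A against D, 1145, 694 and 2028 for the steps from A to D, 840 for middle against ends and 6809 for the F-test, and with the pool as a random effect 7760, 1070, 633, 1929, 789 and 6580, against 7793, 1067, 640, 1863, 767 and 6551 as reported. Renewed quantile normalization, median centring, the filter at the median signal, the intensity trend and the robust prior left each of these totals within 1.5 times. In the upper quartile of mean signal, where fewer probe sets were tested, they were 4252 for A against D, 672 for A against B, 1081 for C against D, 439 for middle against ends and 3683 for the F-test, and the middle-against-ends calls split into 262 higher and 177 lower against 332 and 435. With 1 probe set per gene, again fewer tests, A against D gave 4308 and the F-test 3741. Array weights, lowest for region B replicate 1 (0.38) and region C replicate 3 (0.45), gave 3206 for C against D and 1516 for middle against ends; the cause was not tested. The 6 arrays of B and C alone, which are fewer samples, gave 200.

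Leaving out a pool or an array, which also reduces the number of samples, gave 4844 to 9005 calls for A against D, 324 to 1201 for A against B, 55 to 877 for B against C, 505 to 2644 for C against D, 162 to 1106 for middle against ends and 3149 to 7785 for the F-test, and every lowest value came without replicate 2. Without both region B replicate 1 and region C replicate 3 the counts were 9513, 1241, 617, 2091, 1461 and 8604 in the order A against D, the 3 steps, middle against ends and F-test. Of the fits that leave out 1 pool, only that without replicate 2 keeps both of these arrays. How far that lowers its counts was not tested. Camera called 11 lists for A against D without any 1 of the pools and 8 to 11 for middle against ends. With an estimated correlation it called 0 lists in both comparisons, while fry called 21 and 5. The HOX and CDX list, lower in the middle as reported, had a mean of 0.128 among genes above the median signal and did not pass; the cause was not tested.

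Of 217 values of named genes, 162 kept their direction and side of the threshold in all 8 alternatives tried for them, 42 lost the call in at least 1, 13 gained it and 0 reversed while called. Where neither fit called a gene or list, a change of sign was not counted as a reversal. The arrays give no background signal per probe set, so small differences at low signal have no stated limit.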

Other observations

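The tests on region B replicate 1 and on the yolk endoderm genes were chosen only after the result was seen, while the test on the sizes of the steps and the counts under other splits were chosen before.

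None of the lists of general cell functions passed camera between regions A and D. Their counts are to be read beside the 4308 of 13008 genes called with 1 probe set per gene, adjusted over those genes. Of 34 extracellular matrix genes 9 were higher in A, such as the collagen genes COL1A2 (2.17) and COL2A1 (0.87), and 6 were lower, such as FBLN2 (-1.16) and NID1 (-0.77). The counts were 10 and 9 adjusted over the list alone (adjusted p = 0.535, median -0.01, mean 0.06). The probe sets ranged from 0.05 to 2.17 for COL1A2, from -0.12 to 0.87 for COL2A1 and from -0.77 to -0.30 for NID1. Of 43 cell adhesion and guidance genes 14 were higher in A, such as EPHA4 (1.23) and EPHB3 (1.15), and 7 were lower, such as PLXNA2 (-2.30) and PCDH8 (-1.69). With 14 and 10 adjusted over the list alone, this list had an adjusted p of 0.417 (median -0.02, mean 0.01). Of 17 tight junction and epithelium genes 6 were higher in A, such as CLDN11 (1.15), and the 4 lower were TJP3 (-1.69), KRT7 (-1.21), CDH1 (-0.998) and CGN (-0.30). The probe sets of TJP3 ranged from -1.69 to -0.09. With 7 and 4 adjusted over the list alone, its adjusted p was 0.285.

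Of 30 cell cycle genes CENPF (0.85), CCNB3 (0.30) and CDKN1A (0.28) were higher in A, and CCNE1 (-0.53), CCND3 (-0.49), CDK6 (-0.47), CCNA2 (-0.35) and BUB1 (-0.27) were lower. The probe sets ranged from -0.53 to -0.13 for CCNE1, from -0.49 to -0.14 for CCND3 and from -0.47 to -0.12 for CDK6. The counts of higher and lower genes, 3 and 5, were the same adjusted over the list alone (adjusted p = 0.879, median -0.01, mean -0.01, direction of the test up). In the glycolysis and hypoxia list 2 of 24 were higher in A, CA9 (0.88) and ENO2 (0.30), and 6 were lower, such as VEGFA (-2.26), EPAS1 (-1.78) and GPI (-0.64). With 6 and 8 adjusted over the list alone, its adjusted p was 0.535. None of 42 ribosomal protein genes passed, with counts of 0 and 0 adjusted over the list alone (adjusted p = 0.183, median -0.06). Of 21 stress and apoptosis genes 4 were higher in A, HSPA2 (1.49), GADD45A (0.95), HSPA5 (0.31) and CDKN1A, and 6 were lower, such as GADD45G (-1.96) and MDM2 (-0.85). The counts were the same adjusted over the list alone (adjusted p = 0.792, median 0.00, mean -0.06). The probe sets of MDM2 ranged from -1.22 to -0.04. HSPA5 was the only named gene called between A and D whose direction was not the same in all 3 pools.

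Region B replicate 1 stood apart from its region. Its root-mean-square log2 difference from the other region B arrays was 0.202. The difference was 0.222 from region A, 0.229 from region C and 0.299 from region D. It was thus closest to its own region by a small margin, which argues against a whole sample of another region under this label. A mixture of tissues was not tested. Only 1.4% of its squared difference from the other region B arrays lay along the change from A to C. That argues against a shift of the piece in 1 direction along the streak as the main part of the departure. A smaller shift remains open. GSC had 10.19 in this array, against 9.79 and 9.56 in the other region B arrays. CDX4 had 6.88, against 7.82 and 7.99. Both lay towards region A, as did the other genes with the largest differences between A and D, except EDNRB, which lay between those arrays. A piece cut longer, shorter or wider was not tested. The other arrays of pool 1 lay 0.115 to 0.117 from their regions, the lowest in each, so its pool shared no departure of like size. Its deviation from the region mean correlated at 0.192 with that of the region A array of the pool. The value was 0.076 for the region C array and -0.249 for the region D array. Its 3' minus 5' control signal lay 0.043 above the other region B arrays, with a pooled SD of 0.028, which leaves RNA integrity open.

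Some yolk endoderm and hypoblast genes were higher in region D than in region C. APOA1 (higher by 1.05), FGB (0.78), GATA6 (0.67), HNF4A (0.59) and FGG (0.33) rose in D and CER1 fell by 1.54, while the list as a whole did not pass camera (adjusted p = 0.0889, and adjusted p = 0.434 with an estimated correlation). Over the 23 measured genes the median difference D minus C was 0.092, with quartiles of -0.039 and 0.288. One hypothesis is that lower-layer cells were carried into the posterior pieces, and this cannot be told apart from expression of these genes in the streak itself, because VTN and TF did not pass while APOA1 did. In situ hybridisation for APOA1 and FGB on sections of region D would separate the explanations.

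The steps between neighbouring regions gave unequal numbers of calls, 1067, 640 and 1863. The squared distance between region means, less noise, was 0.0183 from A to B, 0.0134 from B to C and 0.0229 from C to D, and the last was 1.7 times that from B to C. That ratio was 2.97, 1.63 and 0.84 without pools 1, 2 and 3. Pool 3 holds region C replicate 3, which lay towards region B on the first component (4.98, against 12.37 and 13.01 in the other region C arrays). Without this array alone the counts were 877 from B to C and 1356 from C to D. The unequal counts thus depend in part on this array, and where its piece was cut was not tested. A truly larger change from C to D and steps of like size with counts that follow noise cannot be told apart with 3 pools. Further pools of the same pieces would separate them.

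The calls were counted again under other splits of the arrays. For the F-test the real groups gave 6551 calls and the other splits drawn at most 2363. The real split was the only 1 of 100 with as many calls, which makes chance unlikely but does not exclude it. Within pools the highest other was 2855. For middle against ends, with 767 calls, 1 other split of those drawn gave more, 3661, and its groups part the arrays along the A to D axis, with mean positions 1.67 apart against a median of 0.33. The share of splits with as many calls stayed under 0.05, and the next highest split gave 333. Other splits also break up the change from A to D, which then counts as noise. They test for any regional difference and not for this contrast alone, so they do not settle chance here. Among splits drawn within pools, 2 others gave more than the real one, 4180 and 4118, and both part regions A and B from C and D in every pool, with mean positions 2 apart. These large counts point to the structure of the samples along the streak. For the pairs of regions the splits are too few for a share under 0.05. The real and highest other counts were 7793 and 0 for A against D, 1067 and 0 for A against B, 640 and 21 for B against C, and 1863 and 0 for C against D.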
